A study of Mus musculus with 48 samples.

How the data were processed

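RNA of 48 cultures of mouse Kupffer cells and monocytic macrophages was measured on Affymetrix arrays, 1 array per culture, in 16 groups of 3 by cell type, addition and time, per the labels. Total RNA had been extracted with QIAZOL and labelled as biotinylated cRNA by the Affymetrix protocol. The authors deposited log2 signals per probe set, normalized by RMA in the Transcriptome Analysis Console, whose version is not given in the sources used here. The deposited log2 values run from 0.88 to 19.93, where signals are capped, and the arrays do not share 1 distribution. Whether all arrays were normalized together is not stated.

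Of 28846 probe sets, 6640 controls were set aside, and 2634 transcript probe sets without a gene symbol were tested apart. For the 55 genes with several probe sets, the probe set with the highest mean over all arrays was used, which left 19505 genes. No filter on level was applied. Symbols were checked against the RefSeq gene table of GRCm38.p6, used for names only, and no coordinates are given, since the files name no build.

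Each gene was fitted with limma 3.58.1 in R 4.3.3 with the package data.table, version 1.17.8, with 1 mean per group, so that all arrays share 1 estimate of the spread. Empirical Bayes moderation was run with default settings, the moderated test was two-sided, and p was adjusted by Benjamini and Hochberg over all genes within each of the 26 contrasts, with a threshold of 0.05. The contrasts were each addition against the MCSF control of its cell type and time, the controls against each other by cell type and by time, Ito against CD146 cells, and the Kupffer response minus the monocytic response. A gene is said to have risen, fallen, been higher or been lower only where it passed. Replicate numbers were checked for pairing over arrays of different groups: deviations from the group means correlated by -0.0103 on average for equal numbers and 0.0055 for different ones, and all 3 correlations exceeded 0.1 in 1 of 120 pairs of groups, so no pairing was used.

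The 32 gene lists, written before the data were examined like the contrasts, tests and alternatives, cover marker genes of Kupffer cells, monocytes, macrophages in general, Ito cells, sinusoidal endothelial cells, hepatocytes, cholangiocytes, neutrophils, T and NK cells, B cells, dendritic cells, platelets and erythroid cells, and genes of macrophage activation, metabolism, stress and signalling. For each list and contrast the genes past the threshold were counted, over all genes and adjusted over the list alone. Lists were tested with camera from limma at a preset correlation of 0.01, with p adjusted over the lists within a contrast.

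Genes were named by a rule that admits, per contrast, up to 8 with the largest rise and up to 8 with the largest fall among those past the threshold whose groups do not overlap (5 each way by size for the difference of responses), up to 4 members of each described list with the smallest adjusted p, and a fixed set of Kupffer cell, monocyte, growth factor and cytokine genes. Probe sets of unnamed gene models were skipped under the first part, and so were families of near-identical genes (stefins, histones, major urinary proteins), whose probes may not tell them apart. Which of the admitted genes and of the list results are printed was decided for length with their values in view, and list results that fail with an estimated correlation were left out more often. Of 104 list calls printed, 39 are lost with it, and of 217 not printed, 197, so the printed lists look sounder than all of them.

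The tests were tried on data simulated from the monocytic CD146 comparison of 1 day. Of 100 genes changed 2-fold and 100 4-fold, 41 and 97 were recovered, and 12 unchanged genes called. The shifted list was called and 0 of the rest. This leaves open calls in noisier groups and camera on lists whose genes vary together. The alternatives were quantile normalization, median centring of each array, leaving out the dimmest 25 percent of genes, a trend and robust variance model, array weights, the replicate number as a block, all probe sets, a 2-fold minimum, only the arrays compared, leaving out each array in turn, camera with an estimated correlation, fry, and lists without members of other cell type lists. Leaving out the 3 arrays that stood apart was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.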

Results

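The arrays measured transcript levels in cultured mouse macrophages of 2 origins. Kupffer cells, the resident macrophages of the liver, had been sorted from BALB/c males by the F4/80 antigen, and the series design has the blood monocytes, sorted by CD115, come from those same animals. After a first day in MCSF, the growth factor that maintains macrophages, the cells were kept for 1 or 3 more days with an addition or in MCSF as the control. The additions were Ito cells (the vitamin A-storing stellate cells of the liver), CD146 cells (its sinusoidal endothelial cells) and hepatocyte growth factor (HGF). The labels do not say whether the added cells were kept apart from the macrophages or removed before lysis, nor whether MCSF stayed in the medium beside an addition. Each of the 16 groups held 3 arrays, 48 in all, whose titles call the replicates biological. The number of arrays limits the precision. Values in parentheses after a gene are log2 differences of group means (n = 3 each) ± limma SE, and levels are log2 values ± SD. SE and p rest on the spread of all arrays, too small for noisier groups (Kupffer MCSF and HGF, 1 day). Lists of genes had been fixed before the data were examined, and the camera test asks whether the genes of a list differ from all other genes. For each list the text gives how many of its measured genes passed, how many passed when p was adjusted within the list alone (where no second count follows, the first holds there too), and the adjusted p of camera with the preset correlation, followed by that with an estimated correlation ("if estimated") where the call is lost under it.

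Array level and marker genes differed between the groups. The 5th percentile of the genes lay at 2.16 in the monocytic HGF arrays of 1 day, at 2.54 and 2.57 in the Kupffer and monocytic Ito arrays of 1 day, and between 2.80 and 3.01 in the other groups. Their medians (4.29, 4.70 and 4.63) also lay below those of the other groups (4.88 to 5.35). Where the median of all genes moved by over 0.1, that shift is given and gene values are relative to it. Gene calls, their adjusted p and list counts are of differences before it is taken off. Of 426 differences between 2 groups given as passing, 110 had 1 group under its negative control probes (means of 4.85 to 5.65), so that their size before a median shift is taken off is a lower bound, which the SE does not cover, and in 17 of 32 differences of responses some group did, so that a part of these is a difference between background values. Group means of Apoe, Arg1, Cxcl13, Igf1, Lcn2 and Thbs1 came within 1 log2 unit of the highest signal, where a difference may be understated. Genes of a list that passed under the negative controls in all groups compared are counted as at background. The mean level of core macrophage genes was 14 to 15.89 in every group. Genes of sinusoidal endothelial cells averaged 6.72 ± 0.97 and genes of hepatocytes 6.08 ± 0.80 in the Kupffer control of 1 day, against 4.23 ± 0.05 and 3.79 ± 0.14 in that of 3 days. The monocytic controls lay at 4.21 and 3.77 after 1 day and at 4.33 and 3.90 after 3 days. The arrays that stood apart from their groups were 3: Kupffer control 1 day replicate 1, Kupffer HGF 1 day replicate 2 and monocytic control 3 day replicate 3. The first had a mean of 4.34 over the B cell genes, against 9.38 and 10.40 in its group, and the last had a mean of 11.13 over the cell cycle genes, against 6.52 and 6.73.

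**Figure D1:**
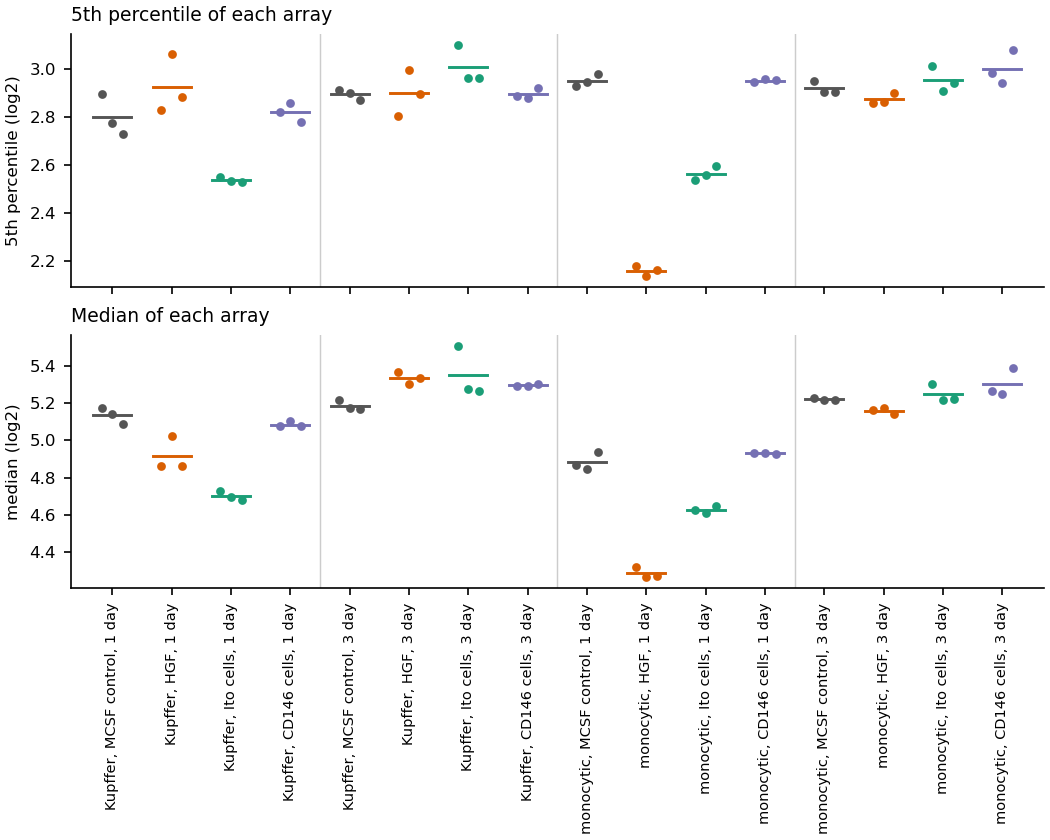
Each point is an array and each bar the mean of a group of 3: the 5th percentile (upper panel) and the median (lower panel) of all genes, in log2 units. The monocytic HGF arrays of 1 day have the lowest values, with a mean 5th percentile of 2.16.

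**Figure D2:**
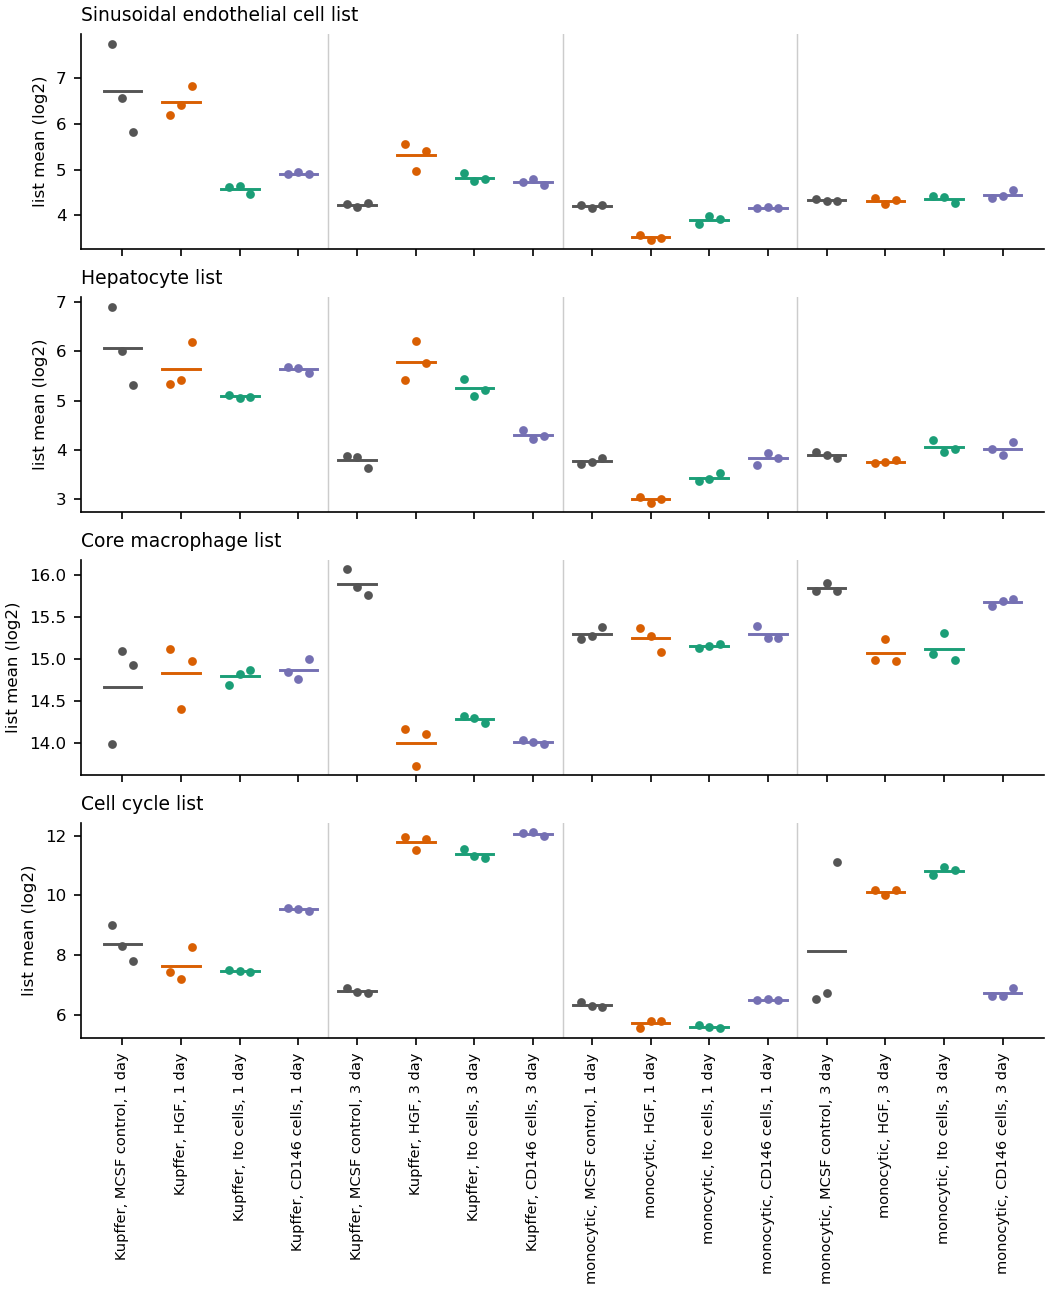
Each point is an array and each bar the mean of a group of 3, in log2 units: the mean level of the genes in the sinusoidal endothelial, hepatocyte, core macrophage and cell cycle lists. The Kupffer control of 3 days has a mean of 6.79 over the cell cycle genes, below the other Kupffer groups of 3 days.

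MCSF controls of Kupffer cells and monocytic macrophages were compared. After 1 day, Kupffer cells were higher in Clu (11.87 ± 0.51), Alb (10 ± 0.47), Adgrl4 (9.90 ± 0.48), Cdh5 (9.44 ± 0.55), Sparc (9.31 ± 0.49) and Cd5l (8.83 ± 0.51), a scavenger protein secreted by Kupffer cells. They were lower in Cxcl13 (-4.33 ± 0.71), a chemokine for B cells, Slc7a2 (-4.31 ± 0.78), Ereg (-4.30 ± 0.62), Il6 (-4.12 ± 0.61) and Cxcl1 (-3.97 ± 0.84), a chemokine for neutrophils. Among 19505 genes, 4157 genes passed, 1897 higher and 2260 lower (1196 and 4849 after median centring). Of the genes fixed in advance, Ly6c2 (3.64 ± 0.47) and Mcam (1.99 ± 0.38), which encodes CD146, were higher and Il1b (-2.84 ± 0.72) and Ccr2 (-1.57 ± 0.45), the receptor of monocyte chemokines, lower, while Timd4 (-0.33 ± 0.35) and Vsig4 (-0.36 ± 0.29) did not pass and the Kupffer cell lectin Clec4f lay below the negative control probes on all 48 arrays. In the Kupffer cell identity list 7 of 19 were higher and 1 lower (10 and 1 within the list, 1 at background, adjusted p = 3.74e-05), with Slc40a1 (5.73 ± 0.47) and Clec1b (2.04 ± 0.28). Of the cell cycle list, 21 of 28 were higher (24 within the list, adjusted p = 3.7e-12, or 0.239 if estimated), with Ccna2 (3.89 ± 0.79). The pro-inflammatory list was lower: 1 of 20 was higher and 10 lower (1 at background, adjusted p = 0.000525, or 0.239 if estimated), with Ptgs2 (-3.19 ± 0.58) and Il1a (-3.34 ± 0.62).

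Genes of other cell types were higher in the Kupffer control of 1 day. In the sinusoidal endothelial list 23 of 25 were higher (25 within the list, 6 at background, adjusted p = 9.38e-32), with Emcn (4.87 ± 0.36). For the hepatocyte list, 13 of 18 were higher (15 within the list, 1 at background, adjusted p = 4.14e-18), with Ambp (3.28 ± 0.30). In the cholangiocyte list 5 of 7 were higher (2 at background, adjusted p = 6.76e-08), with the keratins Krt19 (5.28 ± 0.47) and Krt7 (5.52 ± 0.50). Of the B cell list, 6 of 9 were higher (7 within the list, adjusted p = 0.000172, or 0.267 if estimated), with Cd22 (2.97 ± 0.64, arrays overlapping). The adjusted p of the genes that passed here was at most 0.00986. The count was 2365 without Kupffer replicate 1 and 917 with only the arrays compared. Calls were lost for Ccr2 without Kupffer replicate 1 or monocytic replicate 1 or the 3 arrays (adjusted p from 0.0558 to 0.242) and for the B cell list without Kupffer replicate 3 (adjusted p = 0.086). Ccr2, Cd22, Cxcl13, Mcam and Slc7a2 did not pass with only the arrays compared (adjusted p from 0.0807 to 0.203).

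After 3 days, Kupffer cells were higher than monocytic macrophages in Susd2 (12.67 ± 0.33), Lcn2 (12.36 ± 0.79), Ccl5 (10.95 ± 0.54), Il1b (10.21 ± 0.72), Ly6c2 (9.50 ± 0.47), a surface protein of monocytes, and Cfb (8.12 ± 0.64). Levels were lower for Slc46a3 (-7.08 ± 0.38), Hpgd (-6.40 ± 0.41), Entpd1 (-5.62 ± 0.44), the ectonucleotidase CD39, Gas6 (-5.48 ± 0.44), Slc40a1 (-5.40 ± 0.47) and Mrc1 (-4.99 ± 0.52), the mannose receptor. In this comparison 2355 genes passed, 1244 higher and 1111 lower. Of the fixed genes, Nr1h3 (3.90 ± 0.36), the liver X receptor alpha, Timd4 (2.12 ± 0.35), Nos2 (3.53 ± 0.41) and Met (2.12 ± 0.34), the HGF receptor, were higher and Vsig4 (-4.33 ± 0.29), Cd5l (-2.39 ± 0.51) and Id3 (-3.20 ± 0.68) lower. The whole interferon-stimulated list was higher: 22 of 22 were higher (adjusted p = 1.57e-50), with Ifit1 (5.54 ± 0.36) and Irf7 (6.76 ± 0.51). In the pro-inflammatory list 13 of 20 were higher and 1 lower (15 and 2 within the list, adjusted p = 7.21e-15), with Cxcl9 (4.83 ± 0.25). For the glycolysis and hypoxia list, 13 of 21 were higher and 1 lower (17 and 1 within the list, adjusted p = 1.02e-14), with Slc16a3 (3.02 ± 0.33). The lysosome list was lower: 1 of 16 was higher and 5 lower (1 and 10 within the list, adjusted p = 1.66e-05), with Atp6v0d2 (-4.41 ± 0.47) and Lipa (-2.07 ± 0.29). In the cell cycle list 9 of 28 were lower (1 and 19 within the list, 2 at background, adjusted p = 1.46e-06, or 0.604 if estimated), with Pcna (-1.497 ± 0.31), and without monocytic replicate 3, which had high cell cycle genes, the test pointed the other way. Of the platelet and megakaryocyte list, 3 of 8 were higher and 1 lower (3 and 2 within the list, adjusted p = 0.0827). Largest adjusted p of those that passed: 0.000624. The calls ended for the cell cycle list without monocytic replicate 3 or the 3 arrays (adjusted p from 0.63 to 0.664). Cd5l and Pcna did not pass with only the arrays compared (adjusted p from 0.0539 to 0.132).

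The controls were also compared over time. The median of all genes rose by 0.15 in Kupffer cells, and values are relative to it. From 1 to 3 days, Kupffer cells rose in Susd2 (13.03 ± 0.33), Ccl5 (10.26 ± 0.54), Cxcl13 (9.02 ± 0.71), Hp (7.75 ± 0.40), Mmp2 (7.70 ± 0.24) and Cp (7.06 ± 0.40). They fell in Ccl7 (-10.69 ± 0.65) and Ccl2 (-8.95 ± 0.58), chemokines for monocytes, Alb (-10.51 ± 0.47), Cdh5 (-9.79 ± 0.55), Adgrl4 (-9.14 ± 0.48) and Arg1 (-8.08 ± 0.59), arginase. In all 6197 genes passed, 4201 higher and 1996 lower (3072 and 2930 after quantile normalization). The fixed genes Timd4 (4.12 ± 0.35), Nr1h3 (3.99 ± 0.36), Adgre1 (2.33 ± 0.30), which encodes F4/80, and Csf1r (2.09 ± 0.23), the MCSF receptor, rose, and Cd5l (-4.85 ± 0.51) fell. In the core macrophage list 8 of 14 rose and 1 fell (adjusted p = 0.00734, or 0.284 if estimated), with Aif1 (4.28 ± 0.36). For the alternatively activated list, 15 of 19 fell (1 at background, adjusted p = 3.19e-11), with Mrc1 (-5.32 ± 0.52). Of the lists of other cell types, that of Ito cells rose: 12 of 23 rose and 1 fell (4 at background, adjusted p = 0.00053, or 0.117 if estimated). Others fell. For the sinusoidal endothelial list, 23 of 25 fell (6 at background, adjusted p = 1.35e-23). In the hepatocyte list 15 of 18 fell (3 at background, adjusted p = 2.6e-14). Of the neutrophil list, 2 of 11 rose and 8 fell (3 and 8 within the list, 2 at background, adjusted p = 9.11e-07). In the dendritic cell list 3 of 11 fell (adjusted p = 0.000598). Of the interferon-stimulated list, 21 of 22 rose (adjusted p = 1.23e-11, or 0.097 if estimated). The passing genes named for this contrast had adjusted p of at most 1.19e-08, and the count was 3311 with only the arrays compared. The core macrophage list did not pass with only the arrays compared (adjusted p = 0.0886).

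In monocytic macrophages the median of all genes rose by 0.13 over the same days, and values are again relative to it. They rose in Sparc (9.42 ± 0.49), Atp6v0d2 (8.43 ± 0.47), Bgn (7.62 ± 0.54), Gas6 (7.18 ± 0.44), Ephx1 (6.85 ± 0.42), Igf1 (6.79 ± 0.38), Mfge8 (6.53 ± 0.38) and Cd5l (6.38 ± 0.51). They fell in Ppbp (-13.38 ± 0.50), in the neutrophil chemokines Cxcl5 (-12.20 ± 0.42), Cxcl3 (-10.99 ± 0.69) and Cxcl2 (-10.65 ± 1.18), Ccl12 (-9.998 ± 0.69) and Arg1 (-9.94 ± 0.59). Here 5716 genes passed, 3800 higher and 1916 lower (2833 and 2685 after quantile normalization, 2109 and 4024 after median centring). The fixed genes Vsig4 (3.90 ± 0.29), Id3 (4.92 ± 0.68), Mertk (2.81 ± 0.32) and Hgf (2.30 ± 0.34) rose, and Il1b (-8.64 ± 0.72), Il6 (-7.85 ± 0.61) and Ccr2 (-3.21 ± 0.45) fell. Of the pro-inflammatory list, 1 of 20 rose and 15 fell (1 at background, adjusted p = 1.52e-17), with Ccl2 (-9.47 ± 0.58). In the glycolysis and hypoxia list 1 of 21 rose and 15 fell (1 and 16 within the list, adjusted p = 5.76e-12), with Egln3 (-4.27 ± 0.41). In the list of LXR targets and lipid handling 11 of 14 rose and 1 fell (12 and 1 within the list, 1 at background, adjusted p = 1.18e-05), with Apoe (3.35 ± 0.31) and Lpl (4.04 ± 0.43), lipoprotein lipase. For the Ito cell and myofibroblast list, 14 of 23 rose (3 at background, adjusted p = 4.32e-08), with Acta2 (5.32 ± 0.35). For the immediate early and heat shock list, 1 of 16 rose and 9 fell (adjusted p = 1.18e-05, or 0.142 if estimated). In the Notch list 5 of 13 rose and 2 fell (5 and 3 within the list, 3 at background, adjusted p = 0.56). In the cell cycle list 16 of 28 rose (19 within the list, 1 at background, adjusted p = 8.34e-05, or 0.504 if estimated), of which 1 control array of 3 days held most. Adjusted p was at most 8.54e-07 for the genes said to have risen or fallen. Passing was lost for the cell cycle list without 3 day replicate 3 or the 3 arrays (adjusted p from 0.83 to 0.839). The cell cycle list did not pass with only the arrays compared (adjusted p = 0.0644).

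Cultures with HGF were compared with MCSF controls. In Kupffer cells after 1 day the median of all genes fell by 0.17, and values are relative to it. Among the largest rises were Thbs1 (2.53 ± 0.72), thrombospondin, Ost4 (2.47 ± 0.29), Ppbp (2.36 ± 0.50), Ccl6 (2.17 ± 0.39) and Pmp22 (2.06 ± 0.38). Among the largest falls were Ikzf3 (-3.23 ± 0.42), Psip1 (-2.66 ± 0.61), Foxp1 (-2.60 ± 0.31) and Ets1 (-2.24 ± 0.30). In all 3421 genes passed, 805 higher and 2616 lower (1164 and 1158 after quantile normalization, 2007 and 1233 after median centring). Of the B cell list, 6 of 9 fell (9 within the list, adjusted p = 0.00194, or 0.939 if estimated), with Ms4a1 (-2.51 ± 0.66, arrays overlapping), the B cell antigen CD20. Of the T and NK cell list, 1 of 13 rose and 8 fell (1 and 9 within the list, 1 and 4 also after quantile normalization, 2 at background, adjusted p = 0.0303, or 0.939 if estimated), with Cd4 (-1.81 ± 0.35). Replicate 1 of the control and replicate 2 of HGF stood apart from their groups, the former in its B cell genes. The fixed gene Arg1 (2.09 ± 0.59, arrays overlapping) passed, and Met (-0.68 ± 0.34), Hgf (-0.19 ± 0.34), Il1b (-0.74 ± 0.72) and Il6 (0.41 ± 0.61) did not. Adjusted p of the passing genes was at most 0.0211, and the count was 5412 without HGF replicate 1, 901 without HGF replicate 2, 1264 without the 3 arrays that stood apart and 0 with only the arrays compared (1753 at an unadjusted p under 0.05). Significance was lost for Arg1 and Thbs1 after quantile normalization and without HGF replicate 2 or control replicate 1 or the 3 arrays (adjusted p from 0.0526 to 0.481), for Ccl6 after quantile normalization (adjusted p = 0.0564) and for Ms4a1 without control replicate 2 or 3 (adjusted p from 0.0506 to 0.102). A call did not hold for the T and NK cell list without HGF replicate 1 or 3 or control replicate 2 or 3 (adjusted p from 0.13 to 0.228), for the B cell list without control replicate 3 (adjusted p = 0.132) and for Psip1 without HGF replicate 2 (adjusted p = 0.066). Calls were lost for Pmp22 and Ppbp without the 3 arrays (adjusted p from 0.147 to 0.192). No call of a gene or list named here held with only the arrays compared (adjusted p from 0.056 to 0.574).

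After 3 days with HGF, Kupffer cells were higher than their control in Krt7 (10.55 ± 0.50), a keratin of bile duct cells, Lmo7 (9.80 ± 0.50), Ccl7 (9.64 ± 0.65), Clu (9.29 ± 0.51), Ube2c (8.59 ± 0.76) and Alb (8.39 ± 0.47). They were lower in Cxcl13 (-14.63 ± 0.71), Susd2 (-13.44 ± 0.33), Cfb (-11.33 ± 0.64), Ccl5 (-11.10 ± 0.54), Ly6i (-10.88 ± 0.58), Il1b (-10.35 ± 0.72) and Slc7a2 (-9.37 ± 0.78). In all 5386 genes passed, 2824 higher and 2562 lower (2349 and 3287 after median centring). The control of this comparison, which the other Kupffer comparisons of 3 days share, had a mean of 6.79 over the cell cycle genes, and with HGF nearly the whole list rose: 27 of 28 rose (adjusted p = 5.04e-27, or 0.105 if estimated), with Pcna (4.15 ± 0.31). For the cholesterol synthesis list, 13 of 18 rose (13 and 2 within the list, adjusted p = 1.31e-05, or 0.145 if estimated), with Sqle (3.61 ± 0.32). The fixed genes Cd5l (4.59 ± 0.51), Ccr2 (6.69 ± 0.45) and Met (1.74 ± 0.34) rose, and Timd4 (-4.13 ± 0.35), Nr1h3 (-4.15 ± 0.36), Adgre1 (-3.94 ± 0.30), Csf1r (-1.81 ± 0.23) and Arg1 (-4.27 ± 0.59) fell. In the core macrophage list 10 of 14 fell (adjusted p = 3.69e-07, or 0.0945 if estimated), with Aif1 (-7.04 ± 0.36). Of the complement list, 1 of 13 rose and 9 fell (adjusted p = 5.25e-07, or 0.105 if estimated), with C1ra (-3.38 ± 0.29). For the hepatocyte list, 13 of 18 rose (2 at background, adjusted p = 8.23e-08, or 0.119 if estimated), with Rbp4 (3.88 ± 0.25). In the cholangiocyte list 7 of 7 rose (2 at background, adjusted p = 8.23e-08). For the interferon-stimulated list, 1 of 22 rose and 18 fell (1 and 20 within the list, adjusted p = 1.91e-06, or 0.292 if estimated). Named genes that passed had adjusted p of 8.91e-05 or less. Changes that all 3 additions share cannot be told apart from a peculiarity of the shared control.

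In monocytic macrophages after 1 day with HGF the median of all genes fell by 0.55, the largest shift in the series, and values are relative to it. The immediate early genes Egr1 (-3.72 ± 0.78) and Fos (-2.02 ± 0.50) fell, as did Pank4 (-1.61 ± 0.33), and Pde3a (2.07 ± 0.32), Fst (2.05 ± 0.30), Hnrnpll (1.99 ± 0.31) and Hs1bp3 (1.82 ± 0.25) rose. In all 7307 genes passed, 43 higher and 7264 lower (223 and 212 after quantile normalization, 357 and 276 after median centring), so the direction of most calls depends on the scaling. The count was 3319 without the dimmest 25 percent of genes. In the lysosome list 1 of 16 fell (0 within the list, 0 also after quantile normalization, adjusted p = 1.69e-05, the test pointing up, adjusted p = 0.962 after quantile normalization). Of the core macrophage list, 0 of 14 passed (adjusted p = 0.00014, or 0.296 if estimated, the test pointing up, adjusted p = 0.962 after quantile normalization). No change can be read from the erythroid list, whose means (4.29 in the control and 3.39 with HGF) lay under the negative controls (5.47 and 4.86): 5 of 6 fell (6 within the list, 1 also after quantile normalization, 4 at background, adjusted p = 0.0629). Neither Met (0.63 ± 0.34) nor Hgf (0.11 ± 0.34) passed, and of the cytokines Il1b (-0.34 ± 0.72), Il6 (-0.79 ± 0.61) and Tnf (-1.07 ± 0.87) did not, while Ccr2 (-1.35 ± 0.45) did. The largest adjusted p among the passing genes was 0.00144. A call did not hold after quantile normalization or after median centring for Ccr2 (adjusted p from 0.0739 to 0.107).

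After 3 days with HGF, monocytic macrophages were higher in the monocyte chemokines Ccl12 (7.999 ± 0.69), Ccl7 (7.52 ± 0.65) and Ccl2 (6.95 ± 0.58), Ch25h (6.62 ± 0.96), Mmp13 (5.14 ± 0.45), Arg1 (4.93 ± 0.59) and Mthfd2 (4.26 ± 0.43), an enzyme of mitochondrial folate metabolism. Levels were lower for Thbs1 (-7.06 ± 0.72), Tmem176b (-7.00 ± 0.50), Hp (-6.26 ± 0.40), Sparc (-5.93 ± 0.49), Bgn (-5.04 ± 0.54) and Igfbp7 (-4.86 ± 0.41). In all 2540 genes passed, 1475 higher and 1065 lower. In the glycolysis and hypoxia list 11 of 21 rose (13 within the list, adjusted p = 9.15e-12), with Pgk1 (2.39 ± 0.30). For the integrated stress list, 7 of 16 rose (9 and 1 within the list, adjusted p = 4.9e-06), with Asns (3.73 ± 0.31) and Atf4 (2.24 ± 0.25). In the Ito cell and myofibroblast list 11 of 23 fell (13 within the list, 2 at background, adjusted p = 4.15e-15), with Acta2 (-4.19 ± 0.35). Of the cell cycle list, 22 of 28 rose (26 within the list, adjusted p = 6.4e-15, or 0.218 if estimated), with Bub1 (3.86 ± 0.73, arrays overlapping), against a control in which replicate 3 alone had high cell cycle genes. The fixed genes Cd5l (1.93 ± 0.51), Ccr2 (3.11 ± 0.45) and Cx3cr1 (1.62 ± 0.44, arrays overlapping) rose and Vsig4 (-1.86 ± 0.29), Id3 (-3.53 ± 0.68, arrays overlapping), Csf1r (-1.97 ± 0.23) and Mertk (-2.68 ± 0.32) fell, with Id3 of HGF replicate 3 at 9.16, a level of the control. Adjusted p for the passing genes was at most 0.00946, and the count was 1239 without control replicate 1, 1420 without control replicate 2, 1591 without HGF replicate 3, 4354 without the 3 arrays that stood apart and 1294 with only the arrays compared. Calls were lost for Cx3cr1 without HGF replicate 2 or control replicate 1 or 2 (adjusted p from 0.0587 to 0.136) and for Cd5l without HGF replicate 3 or control replicate 3 (adjusted p from 0.061 to 0.137). Bub1, Cd5l, Cx3cr1 and Id3 did not pass with only the arrays compared (adjusted p from 0.0753 to 0.135).

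The Kupffer response to HGF minus the monocytic one was also tested. After 3 days 2964 genes passed, 1479 higher and 1485 lower (1134 and 2175 after median centring). The Kupffer response was the higher for Krt7 (11.30 ± 0.70), Clu (11.26 ± 0.73) and Lmo7 (9.32 ± 0.71) and the lower for Susd2 (-12.52 ± 0.46), Ch25h (-11.89 ± 1.36) and Cxcl13 (-10.09 ± 1.01). In the interferon-stimulated list 18 of 22 were lower (19 within the list, adjusted p = 6.67e-12, or 0.091 if estimated). In the glycolysis and hypoxia list 1 of 21 was higher and 15 lower (1 and 17 within the list, adjusted p = 1.37e-12). Of the cholesterol synthesis list, 12 of 18 were higher (adjusted p = 4.5e-10). For the cell cycle list, 22 of 28 were higher (24 within the list, adjusted p = 1.72e-13, or 0.17 if estimated). After 1 day 4515 genes passed, 4074 higher and 441 lower (508 and 545 after quantile normalization, 1513 and 1101 after median centring), with a median of 0.36 over all genes, and relative to it the response was lower for Cir1 (-3.85 ± 0.48), Tnfrsf13c (-3.79 ± 0.995) and Hnrnpll (-3.34 ± 0.44). This count was 561 with only the arrays compared and 1194 without the dimmest 25 percent of genes. In the B cell list 0 of 9 passed (adjusted p = 0.000368, or 0.892 if estimated, the test pointing down). The calls ended for Tnfrsf13c and the B cell list without Kupffer control replicate 3 (adjusted p from 0.0578 to 0.0755). Tnfrsf13c did not pass with only the arrays compared (adjusted p = 0.242).

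Cultures with Ito cells were compared with MCSF controls. In Kupffer cells after 1 day the median of all genes fell by 0.24, and values are relative to it. Rises were largest in Inhba (7.59 ± 0.43), which encodes a subunit of activin, Il6 (7.21 ± 0.61), Atp6v0d2 (6.85 ± 0.47), Ngp (6.24 ± 0.45), Il1b (6.10 ± 0.72), Ereg (5.99 ± 0.62) and Il1f9 (5.99 ± 0.29), a cytokine of the IL-1 family. Falls were largest in Cd5l (-8.61 ± 0.51), F8 (-5.87 ± 0.42), coagulation factor VIII, Adgrl4 (-5.73 ± 0.48), Aqp1 (-5.42 ± 0.52) and Mest (-4.75 ± 0.40). In all 4584 genes passed, 1067 higher and 3517 lower (1611 and 1558 after quantile normalization, 3064 and 1010 after median centring). Of the pro-inflammatory list, 14 of 20 rose (14 and 1 within the list, adjusted p = 1.95e-23), with Cxcl9 (4.64 ± 0.25). For the neutrophil list, 8 of 11 rose and 1 fell (9 and 2 within the list, adjusted p = 4.15e-13), with Ltf (4.41 ± 0.26). In the alternatively activated list 8 of 19 rose (8 and 1 within the list, adjusted p = 2.84e-08), with Chil3 (5.81 ± 0.40). In the Kupffer cell identity list 11 of 19 fell (12 within the list, 1 at background, adjusted p = 4.41e-07), with Vsig4 (-3.80 ± 0.29) and Folr2 (-3.07 ± 0.39). The sinusoidal endothelial list fell: 25 of 25 fell (8 at background, adjusted p = 4.05e-20), with Emcn (-3.90 ± 0.36). Of the hepatocyte list, 11 of 18 fell (12 within the list, 5 also after quantile normalization, 3 at background, adjusted p = 0.000839, or 0.37 if estimated), with Ambp (-2.70 ± 0.30). In the Ito cell list itself 2 of 23 rose and 7 fell (2 and 4 also after quantile normalization, 3 at background, adjusted p = 0.77), with Dcn (2.88 ± 0.48) and Hgf (2.12 ± 0.34) up and Bgn (-2.65 ± 0.54) and Lox (-1.53 ± 0.33) down. The fixed genes Ly6c2 (4.00 ± 0.47), Met (2.41 ± 0.34) and Nos2 (2.79 ± 0.41) rose and Timd4 (-1.36 ± 0.35) and Mcam (-1.18 ± 0.38) fell. Passing genes had adjusted p of at most 0.00546, and the count was 1614 with only the arrays compared. Passing was lost after median centring for Mcam (adjusted p = 0.0535) and without control replicate 1 or without the 3 arrays that stood apart for Mcam and the hepatocyte list (adjusted p from 0.0995 to 0.201). Bgn, Lox and Mcam did not pass with only the arrays compared (adjusted p from 0.0514 to 0.196).

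After 3 days with Ito cells, Kupffer cells were higher in genes of neutrophil granules, Ngp (11.21 ± 0.45), Mpo (10.84 ± 0.54), Elane (9.95 ± 0.50), Prtn3 (9.21 ± 0.43) and S100a9 (8.36 ± 0.46), and in the chemokines Ccl7 (10.43 ± 0.65) and Ccl2 (8.72 ± 0.58), relative to a median shift of 0.11 over all genes. They were lower in Cxcl13 (-14.06 ± 0.71), Susd2 (-13.57 ± 0.33), Ccl5 (-12.46 ± 0.54), Cfb (-10.97 ± 0.64), Il1b (-10.72 ± 0.72), Marco (-10.15 ± 0.71) and Slc7a2 (-9.99 ± 0.78). Susd2 was high in the shared Kupffer control alone. In all 5219 genes passed, 2820 higher and 2399 lower (2058 and 2988 after median centring). For the neutrophil list, 7 of 11 rose and 1 fell (7 and 2 within the list, adjusted p = 1.25e-07). For the cell cycle list, 27 of 28 rose (adjusted p = 4.02e-24, or 0.135 if estimated), with Pcna (3.93 ± 0.31). The fixed genes Arg1 (2.99 ± 0.59), Ccr2 (5.63 ± 0.45) and Met (1.54 ± 0.34) rose, and Timd4 (-4.16 ± 0.35), Vsig4 (-3.27 ± 0.29), Adgre1 (-4.17 ± 0.30) and Csf1r (-1.81 ± 0.23) fell. Of the Ito cell and myofibroblast list, 3 of 23 rose and 8 fell (4 and 9 within the list, 2 at background, adjusted p = 0.0206, or 0.306 if estimated), with Lox (-2.97 ± 0.33). For the hepatocyte list, 12 of 18 rose (13 within the list, 6 at background, adjusted p = 4.5e-05, or 0.211 if estimated), with Alb (8.08 ± 0.47). In the interferon-stimulated list 1 of 22 rose and 17 fell (1 and 18 within the list, adjusted p = 4.62e-10, or 0.148 if estimated). Adjusted p of these passing genes was at most 0.00021.

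In monocytic macrophages after 1 day with Ito cells the median of all genes fell by 0.28, and values are relative to it. Rises were largest in Fst (6.18 ± 0.30), Inhba (5.51 ± 0.43), Scimp (4.57 ± 0.38), Hdc (3.93 ± 0.30), histidine decarboxylase, Upp1 (3.86 ± 0.68) and Socs1 (3.84 ± 0.50), an inhibitor of cytokine signalling. Falls were largest in Cxcl13 (-5.07 ± 0.71), Retnlg (-4.81 ± 0.58), Nxpe5 (-4.09 ± 0.68), Cbr2 (-3.89 ± 0.64), Vsig4 (-3.36 ± 0.29), Pik3r5 (-3.27 ± 0.43) and Hpgds (-3.12 ± 0.27), a prostaglandin D synthase. In all 3029 genes passed, 373 higher and 2656 lower (912 and 847 after quantile normalization, 681 and 753 after median centring). In the Kupffer cell identity list 9 of 19 fell (5 also after quantile normalization, 3 at background, adjusted p = 0.00104, or 0.294 if estimated), with Il18bp (-1.79 ± 0.28) and Folr2 (-2.12 ± 0.39). In the efferocytosis list 1 of 18 rose and 3 fell (1 at background, adjusted p = 0.944), with Gas6 (-2.47 ± 0.44). For the pro-inflammatory list, 4 of 20 rose and 1 fell (5 and 1 within the list, adjusted p = 0.00104, or 0.369 if estimated, adjusted p = 0.12 after quantile normalization). The fixed genes Il1b (2.96 ± 0.72) and Il6 (2.57 ± 0.61) rose and Ccr2 (-2.59 ± 0.45) and Timd4 (-1.39 ± 0.35) fell, while Arg1 (0.43 ± 0.59), near the highest signal, Nos2 (1.29 ± 0.41) and Tnf (-1.54 ± 0.87) did not pass. The passing genes had an adjusted p of 0.00921 or less, and the count was 1793 without control replicate 1, 1846 without control replicate 2, 1829 without Ito replicate 2 and 1865 without Ito replicate 3. Significance was lost for Il1b without control replicate 1 (adjusted p = 0.0643) and for Il6 without control replicate 3 (adjusted p = 0.0577).

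After 3 days with Ito cells, monocytic macrophages were higher in Ccl7 (7.49 ± 0.65), Ccl2 (7.39 ± 0.58), Arg1 (7.34 ± 0.59), Ccl12 (6.95 ± 0.69), Ch25h (6.85 ± 0.96), Slco4a1 (5.29 ± 0.50) and Bub1 (4.48 ± 0.73), a mitotic checkpoint kinase. Those lower were Sparc (-8.01 ± 0.49), Tmem176b (-6.39 ± 0.50), Bgn (-6.35 ± 0.54), Adgre4 (-5.84 ± 0.39), Csf3r (-5.65 ± 0.68), the G-CSF receptor, Cxcl13 (-5.62 ± 0.71) and Id3 (-5.24 ± 0.68). In all 2431 genes passed, 1131 higher and 1300 lower. Of the Ito cell and myofibroblast list, 11 of 23 fell (12 within the list, 1 at background, adjusted p = 8.94e-14), with Acta2 (-3.66 ± 0.35). Of the iron handling list, 1 of 16 rose and 7 fell (1 and 9 within the list, adjusted p = 0.000245), with Slc40a1 (-4.90 ± 0.47). In the cell cycle list 25 of 28 rose (28 within the list, adjusted p = 8.39e-25, or 0.0915 if estimated), with Mcm2 (3.44 ± 0.52), against a control in which 1 array had high cell cycle genes. For the ERK feedback list, 8 of 16 rose (10 within the list, adjusted p = 1.52e-07), with Myc (3.77 ± 0.49). The fixed genes Cd5l (2.55 ± 0.51), Ccr2 (1.69 ± 0.45) and Met (1.503 ± 0.34) rose and Csf1r (-1.47 ± 0.23), Mertk (-2.39 ± 0.32) and Hgf (-1.55 ± 0.34, arrays overlapping) fell. Adjusted p was at most 0.00782 for those that passed, and the count was 1262 without control replicate 1, 1299 without control replicate 2, 4064 without the 3 arrays that stood apart and 1410 with only the arrays compared. A call did not hold for Ccr2 without control replicate 1 (adjusted p = 0.0628). Bub1, Cd5l, Hgf and Mcm2 did not pass with only the arrays compared (adjusted p from 0.0538 to 0.1).

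The Kupffer response to Ito cells minus the monocytic one was tested in the same way. After 1 day 730 genes passed, 360 higher and 370 lower (767 and 261 after median centring), and the Kupffer response was the higher for Atp6v0d2 (6.14 ± 0.67), Chil3 (5.12 ± 0.56), Cxcl10 (5.05 ± 0.86) and Il6 (4.68 ± 0.86) and the lower for Cd5l (-8.51 ± 0.71), Adgrl4 (-8.02 ± 0.68) and F8 (-5.94 ± 0.59). In the pro-inflammatory list 9 of 20 were higher (15 within the list, adjusted p = 5.33e-15). Of the neutrophil list, 7 of 11 were higher (8 and 1 within the list, adjusted p = 2.51e-09). For the sinusoidal endothelial list, 13 of 25 were lower (19 within the list, 2 at background, adjusted p = 9.09e-23). The 1 day count was 454 without Kupffer control replicate 1, 1465 without Kupffer control replicate 3, 420 without monocytic control replicate 2, 449 without monocytic Ito replicate 3 and 371 with only the arrays compared.

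After 3 days 1706 genes passed, 894 higher and 812 lower (696 and 958 after median centring), higher for Ngp (12 ± 0.64), Slc40a1 (10.98 ± 0.66) and Mpo (10.86 ± 0.76) and lower for Ch25h (-13.25 ± 1.36), Susd2 (-12.65 ± 0.46) and Prg4 (-11.50 ± 1.30). In the glycolysis and hypoxia list 1 of 21 was higher and 12 lower (1 and 15 within the list, adjusted p = 1.51e-12). Of the neutrophil list, 7 of 11 were higher (adjusted p = 7.28e-15).

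Cultures with CD146 cells were compared with MCSF controls. In Kupffer cells after 1 day, granule genes of neutrophils, Ngp (4.93 ± 0.45), Mpo (4.15 ± 0.54) and Elane (3.94 ± 0.50), rose, as did Olr1 (3.65 ± 0.47), Prg4 (3.22 ± 0.92), Tgfb2 (3.16 ± 0.43) and Olfml3 (3.05 ± 0.35). Falls were largest in Cd5l (-6.74 ± 0.51), Cd55b (-5.14 ± 0.43), Car8 (-4.95 ± 0.47), Igfbp7 (-4.73 ± 0.41), Selp (-4.71 ± 0.47), P-selectin, Cdh5 (-4.48 ± 0.55) and Ccl6 (-4.20 ± 0.39). In all 737 genes passed, 258 higher and 479 lower. In the sinusoidal endothelial list 16 of 25 fell (22 within the list, 3 at background, adjusted p = 1.8e-41), with Stab2 (-3.82 ± 0.31) and Pecam1 (-3.79 ± 0.37), although such cells had been added. In the B cell list 9 of 9 fell (adjusted p = 7.97e-16), with Ebf1 (-3.13 ± 0.63, arrays overlapping), against a control of which replicate 1 had low B cell genes. For the neutrophil list, 7 of 11 rose and 1 fell (1 at background, adjusted p = 9.03e-12), with Ltf (2.47 ± 0.26). In the NRF2 list 5 of 13 rose (6 within the list, adjusted p = 3.22e-07), with Nqo1 (1.56 ± 0.35). In the blood monocyte list 6 of 15 rose (9 and 1 within the list, adjusted p = 2.27e-05). Of the pro-inflammatory list, 6 of 20 fell (7 within the list, adjusted p = 7.22e-09). The fixed genes Ly6c2 (2.88 ± 0.47) and Ccr2 (1.68 ± 0.45) rose and Il1b (-2.52 ± 0.72) and Il6 (-2.60 ± 0.61) fell. Passing genes here had adjusted p of at most 0.0373, and the count was 448 without CD146 replicate 1, 433 without CD146 replicate 2, 1685 without the 3 arrays that stood apart and 78 with only the arrays compared. Calls were lost for Ccr2 without CD146 replicate 1 or 2 or control replicate 1 or the 3 arrays (adjusted p from 0.0897 to 0.31), for Il1b without CD146 replicate 1 or 2 or 3 or control replicate 1 or 2 or 3 (adjusted p from 0.0585 to 0.155) and for Prg4 without CD146 replicate 1 or 2 or 3 or control replicate 1 or the 3 arrays (adjusted p from 0.0933 to 0.619). The calls ended for the blood monocyte list without control replicate 1 or the 3 arrays (adjusted p from 0.0904 to 0.12), for Il6 without CD146 replicate 2 or control replicate 3 (adjusted p from 0.0573 to 0.0925) and for Nqo1 without control replicate 3 (adjusted p = 0.0777). Car8, Ccr2, Cdh5, Ebf1, Il6, Nqo1, Olr1, Pecam1 and Prg4 did not pass with only the arrays compared (adjusted p from 0.0781 to 0.696).

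After 3 days with CD146 cells, Kupffer cells were higher in Krt7 (9.53 ± 0.50), Ube2c (8.59 ± 0.76), Ccl7 (8.53 ± 0.65), Cdca3 (8.42 ± 0.77) and Clu (8.33 ± 0.51). They were lower in Cxcl13 (-14.09 ± 0.71), Susd2 (-13.45 ± 0.33), Cfb (-11.72 ± 0.64), Ly6i (-10.98 ± 0.58), Il1b (-10.79 ± 0.72), Marco (-10.63 ± 0.71), Ccl5 (-10.62 ± 0.54) and Apoe (-10.57 ± 0.31). In all 5147 genes passed, 2729 higher and 2418 lower. In the cell cycle list 27 of 28 rose (adjusted p = 1.38e-29, or 0.0876 if estimated), with Pcna (3.90 ± 0.31). For the interferon-stimulated list, 2 of 22 rose and 13 fell (2 and 15 within the list, adjusted p = 0.000571, or 0.462 if estimated). In the core macrophage list 8 of 14 fell (adjusted p = 9.66e-06, or 0.0876 if estimated), with Aif1 (-8.23 ± 0.36). In the sinusoidal endothelial list 5 of 25 rose (4 within the list, 2 at background, adjusted p = 0.0947), with Emcn (2.92 ± 0.36) and Kdr (2.84 ± 0.45). For the cholangiocyte list, 5 of 7 rose (1 at background, adjusted p = 8.53e-05, or 0.0876 if estimated), with Krt19 (5.53 ± 0.47). In the matrix remodelling list 5 of 17 rose and 10 fell (adjusted p = 0.0527). The fixed genes Ccr2 (5.86 ± 0.45) and Il10 (2.60 ± 0.41) rose and Vsig4 (-6.34 ± 0.29), Timd4 (-3.83 ± 0.35), Adgre1 (-3.88 ± 0.30), Csf1r (-1.12 ± 0.23) and Arg1 (-5.07 ± 0.59) fell. Adjusted p of the genes that passed did not exceed 0.00019.

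In monocytic macrophages after 1 day with CD146 cells, Igf1 (5.45 ± 0.38), insulin-like growth factor 1, Olfml3 (4.82 ± 0.35), Gsta3 (4.11 ± 0.40), Lcn2 (3.71 ± 0.79), Tgfb2 (3.19 ± 0.43) and Nqo1 (2.97 ± 0.35), rose. Falls were largest in Selp (-5.83 ± 0.47), Il6 (-5.31 ± 0.61), Nrg1 (-4.90 ± 0.46), Ccl24 (-4.60 ± 0.65), Ccl6 (-4.58 ± 0.39), Tnfsf14 (-4.24 ± 0.33) and Il1a (-3.85 ± 0.62). In all 455 genes passed, 196 higher and 259 lower. Of the interferon-stimulated list, 10 of 22 fell (16 within the list, adjusted p = 4.33e-19), with Usp18 (-2.65 ± 0.33). In the pro-inflammatory list 8 of 20 fell (1 and 10 within the list, adjusted p = 5.31e-15), with Ccl4 (-3.07 ± 0.46). In the alternatively activated list 7 of 19 fell (1 and 7 within the list, adjusted p = 8.99e-10), with Mrc1 (-3.70 ± 0.52). For the cholesterol synthesis list, 6 of 18 rose (11 within the list, adjusted p = 2.23e-13), with Fdft1 (2.15 ± 0.30). Of the NRF2 list, 4 of 13 rose (6 and 1 within the list, adjusted p = 2.72e-07, or 0.0575 if estimated). The fixed gene Vsig4 (1.34 ± 0.29) rose and Il1b (-2.60 ± 0.72) fell. Adjusted p of those genes was at most 0.0369, and the count was 295 without control replicate 2, 280 without CD146 replicate 1 and 294 without CD146 replicate 3. The calls ended for Il1b without CD146 replicate 1 or 2 or 3 or control replicate 2 or 3 (adjusted p from 0.0898 to 0.236).

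After 3 days with CD146 cells, monocytic macrophages were higher in Arg1 (6.41 ± 0.59), Fxyd2 (5.36 ± 0.58), Slco4a1 (4.74 ± 0.50), Ccl8 (4.22 ± 0.50), Selp (4.07 ± 0.47), Slc6a12 (3.90 ± 0.64) and Mmp13 (3.86 ± 0.45). Lower were Id3 (-5.08 ± 0.68), Itgal (-4.84 ± 0.32), Sparc (-3.83 ± 0.49), Acta2 (-3.43 ± 0.35), Ube2c (-3.33 ± 0.76), Timp3 (-3.04 ± 0.46) and Pbk (-2.87 ± 0.67). In all 468 genes passed, 237 higher and 231 lower (180 and 304 after median centring). In the glycolysis and hypoxia list 12 of 21 rose (16 within the list, adjusted p = 2.04e-22), with Egln3 (3.37 ± 0.41). Of the cholesterol synthesis list, 8 of 18 fell (11 within the list, adjusted p = 1.11e-14), with Sqle (-1.81 ± 0.32). In the Ito cell and myofibroblast list 9 of 23 fell (adjusted p = 7.02e-12), with Col1a2 (-2.76 ± 0.36). Of the TGF-beta and BMP list, 3 of 14 fell (5 within the list, 1 at background, adjusted p = 1.33e-05), with Smad6 (-1.82 ± 0.34). In the cell cycle list 0 of 28 passed (0 and 18 within the list, adjusted p = 1.13e-15, or 0.154 if estimated, the test pointing down), and without control replicate 3, which had high cell cycle genes, it pointed the other way. For the interferon-stimulated list, 8 of 22 rose (15 within the list, adjusted p = 2.11e-12, or 0.111 if estimated). The fixed genes Ly6c2 (2.42 ± 0.47), Ccr2 (2.15 ± 0.45) and Met (1.82 ± 0.34) rose and Vsig4 (-1.28 ± 0.29) fell. Adjusted p was no more than 0.0105 for passing genes, and the count was 274 without CD146 replicate 2, 246 without CD146 replicate 3, 978 without the 3 arrays that stood apart and 205 with only the arrays compared. Passing was lost without control replicate 3 for Pbk, Ube2c and the cell cycle list (adjusted p from 0.0758 to 0.516), without CD146 replicate 2 for Vsig4 (adjusted p = 0.05) and without CD146 replicate 3 for Ccr2 and Pbk (adjusted p from 0.0559 to 0.0574). Significance was lost without the 3 arrays that stood apart for Pbk and the cell cycle list (adjusted p from 0.0761 to 0.615). Ccr2, Ly6c2, Pbk and Ube2c did not pass with only the arrays compared (adjusted p from 0.0752 to 0.354).

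The Kupffer response to CD146 cells minus the monocytic one differed after 3 days in 3545 genes, 1880 higher and 1665 lower. It was higher for Ube2c (11.92 ± 1.08) and Cdca3 (10.56 ± 1.09) and lower for Cxcl13 (-14.16 ± 1.01), Susd2 (-12.75 ± 0.46) and Ly6i (-12.50 ± 0.83). For the cell cycle list, 27 of 28 were higher (28 within the list, adjusted p = 4.57e-39), partly from monocytic control replicate 3. For the cholesterol synthesis list, 13 of 18 were higher (14 and 1 within the list, adjusted p = 2.97e-12).

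After 1 day 171 genes passed, 32 higher and 139 lower, higher for Ngp (3.77 ± 0.64) and Elane (3.62 ± 0.70) and lower for Cd5l (-7.26 ± 0.71), Cd55b (-5.51 ± 0.60) and Igfbp7 (-5.14 ± 0.58). In the sinusoidal endothelial list 11 of 25 were lower (17 within the list, 1 at background, adjusted p = 1.72e-37). The count of 1 day was 265 without Kupffer control replicate 1, 259 without Kupffer control replicate 3, 457 without the 3 arrays that stood apart and 70 with only the arrays compared.

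The comparisons with a control share that control and were not set against each other. Instead, cultures with Ito and with CD146 cells were compared directly. In Kupffer cells after 1 day the median of all genes moved by -0.27, and values are relative to it. Levels were higher with Ito cells for Il6 (9.83 ± 0.61), Inhba (9.29 ± 0.43), Il1a (8.80 ± 0.62), Il1b (8.65 ± 0.72), Ereg (6.97 ± 0.62) and Osm (6.79 ± 0.53), oncostatin M, and lower for Mpo (-5.44 ± 0.54), Nav2 (-5.40 ± 0.33), Lpl (-4.34 ± 0.43), Gsta3 (-4.29 ± 0.40) and Treml4 (-4.14 ± 0.49). In all 5349 genes passed, 1288 higher and 4061 lower (1894 and 1973 after quantile normalization, 2716 and 1253 after median centring). Of the pro-inflammatory list, 16 of 20 were higher (adjusted p = 1.64e-32), with Cxcl9 (5.09 ± 0.25). In the alternatively activated list 12 of 19 were higher (14 and 1 within the list, adjusted p = 3.3e-17), with Ccl17 (5.18 ± 0.35). Of the matrix remodelling list, 10 of 17 were higher and 1 lower (1 at background, adjusted p = 1.13e-09), with Mmp13 (6.08 ± 0.45). The fixed genes Hgf (2.44 ± 0.34) and Nos2 (3.48 ± 0.41) were higher and Vsig4 (-2.88 ± 0.29), Cd5l (-1.84 ± 0.51) and Ccr2 (-2.13 ± 0.45) lower. Passing genes had adjusted p of 0.00182 or below.

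After 3 days 601 genes passed, 301 higher and 300 lower between Kupffer cells with Ito cells and with CD146 cells. With Ito cells Ppbp (8.47 ± 0.50) and Pf4 (6.72 ± 0.36), platelet chemokines, Arg1 (8.17 ± 0.59), S100a8 (6.07 ± 0.57), Ccl8 (5.999 ± 0.50), Cxcl3 (5.69 ± 0.69) and Ngp (5.49 ± 0.45) were higher and Pltp (-3.97 ± 0.70), Cxcl10 (-3.69 ± 0.61), Upk3b (-3.62 ± 0.28), Cd72 (-3.51 ± 0.61) and Axl (-3.27 ± 0.46) lower. In the neutrophil list 8 of 11 were higher (1 at background, adjusted p = 2.38e-28), with Elane (4.57 ± 0.50). In the platelet and megakaryocyte list 3 of 8 were higher (4 within the list, adjusted p = 6.94e-12). For the Ito cell and myofibroblast list, 8 of 23 were lower (1 and 9 within the list, adjusted p = 1.53e-06), with Dcn (-3.09 ± 0.48) and Sparc (-2.86 ± 0.49), although Ito cells had been added. Of the fixed genes, Vsig4 (3.19 ± 0.29), Ly6c2 (2.00 ± 0.47) and Nos2 (2.00 ± 0.41) were higher and Cx3cr1 (-2.54 ± 0.44) lower. The adjusted p values of passing genes were at most 0.00732, and the count was 351 without CD146 replicate 1 and 393 without Ito replicate 3. Significance was lost for Ly6c2 without CD146 replicate 1 or Ito replicate 3 (adjusted p from 0.0569 to 0.0599).

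In monocytic macrophages after 1 day the median moved by -0.30, and values are relative to it. With Ito cells Fst (7.96 ± 0.30), Il6 (7.89 ± 0.61), Inhba (7.81 ± 0.43), Tnfrsf9 (5.89 ± 0.56), Il1a (5.76 ± 0.62) and Il1b (5.59 ± 0.72) were higher and Igf1 (-7.30 ± 0.38), Cxcl13 (-5.56 ± 0.71), Olfml3 (-5.08 ± 0.35), Cbr2 (-4.78 ± 0.64), Vsig4 (-4.68 ± 0.29) and Gsta3 (-4.53 ± 0.40) lower. In all 3858 genes passed, 585 higher and 3273 lower (1220 and 1185 after quantile normalization, 1094 and 939 after median centring). In the pro-inflammatory list 12 of 20 were higher and 2 lower (13 and 3 within the list, adjusted p = 3.03e-16), with Il12a (4.31 ± 0.41). For the alternatively activated list, 8 of 19 were higher and 1 lower (9 and 1 within the list, adjusted p = 1.35e-10). In the interferon-stimulated list 9 of 22 were higher (11 within the list, adjusted p = 6.24e-15, or 0.0861 if estimated). The fixed genes Ccr2 (-1.61 ± 0.45) and Mertk (-0.84 ± 0.32) were lower. No passing gene named here had an adjusted p above 0.0102, and the count was 2546 without CD146 replicate 2 and 2375 without CD146 replicate 3. A call did not hold after median centring or without Ito replicate 3 for Mertk (adjusted p from 0.0561 to 0.0908).

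After 3 days 2207 genes passed, 1136 higher and 1071 lower in monocytic macrophages. With Ito cells Ch25h (7.15 ± 0.96), Ccl7 (6.77 ± 0.65), Ube2c (6.49 ± 0.76), Ccna2 (6.42 ± 0.79), Cdca3 (6.30 ± 0.77) and Egr1 (5.90 ± 0.78) were higher and Tmem176b (-6.60 ± 0.50), Cxcl13 (-5.69 ± 0.71), Arg2 (-5.57 ± 0.53), Csf3r (-5.03 ± 0.68), Hp (-4.60 ± 0.40) and Fcgrt (-4.27 ± 0.39) lower. The whole cell cycle list was higher: 28 of 28 were higher (adjusted p = 1.36e-51), with Mcm6 (3.98 ± 0.46) and Kif11 (5.65 ± 0.69). Of the interferon-stimulated list, 19 of 22 were lower (adjusted p = 9.14e-23), with Oas2 (-3.35 ± 0.37). For the MHC class II list, 4 of 10 were lower (adjusted p = 0.0221, or 0.761 if estimated), with H2-Ab1 (-3.62 ± 0.71). The fixed genes Cd5l (4.43 ± 0.51) and Vsig4 (1.33 ± 0.29) were higher and Csf1r (-1.28 ± 0.23), Mertk (-1.72 ± 0.32) and Hgf (-1.54 ± 0.34) lower, while Arg1 (0.93 ± 0.59) did not pass. Their adjusted p was at most 0.00134 where they passed. Calls were lost for the MHC class II list without CD146 replicate 2 or Ito replicate 1 (adjusted p from 0.0504 to 0.0552).

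**Figure D3:**
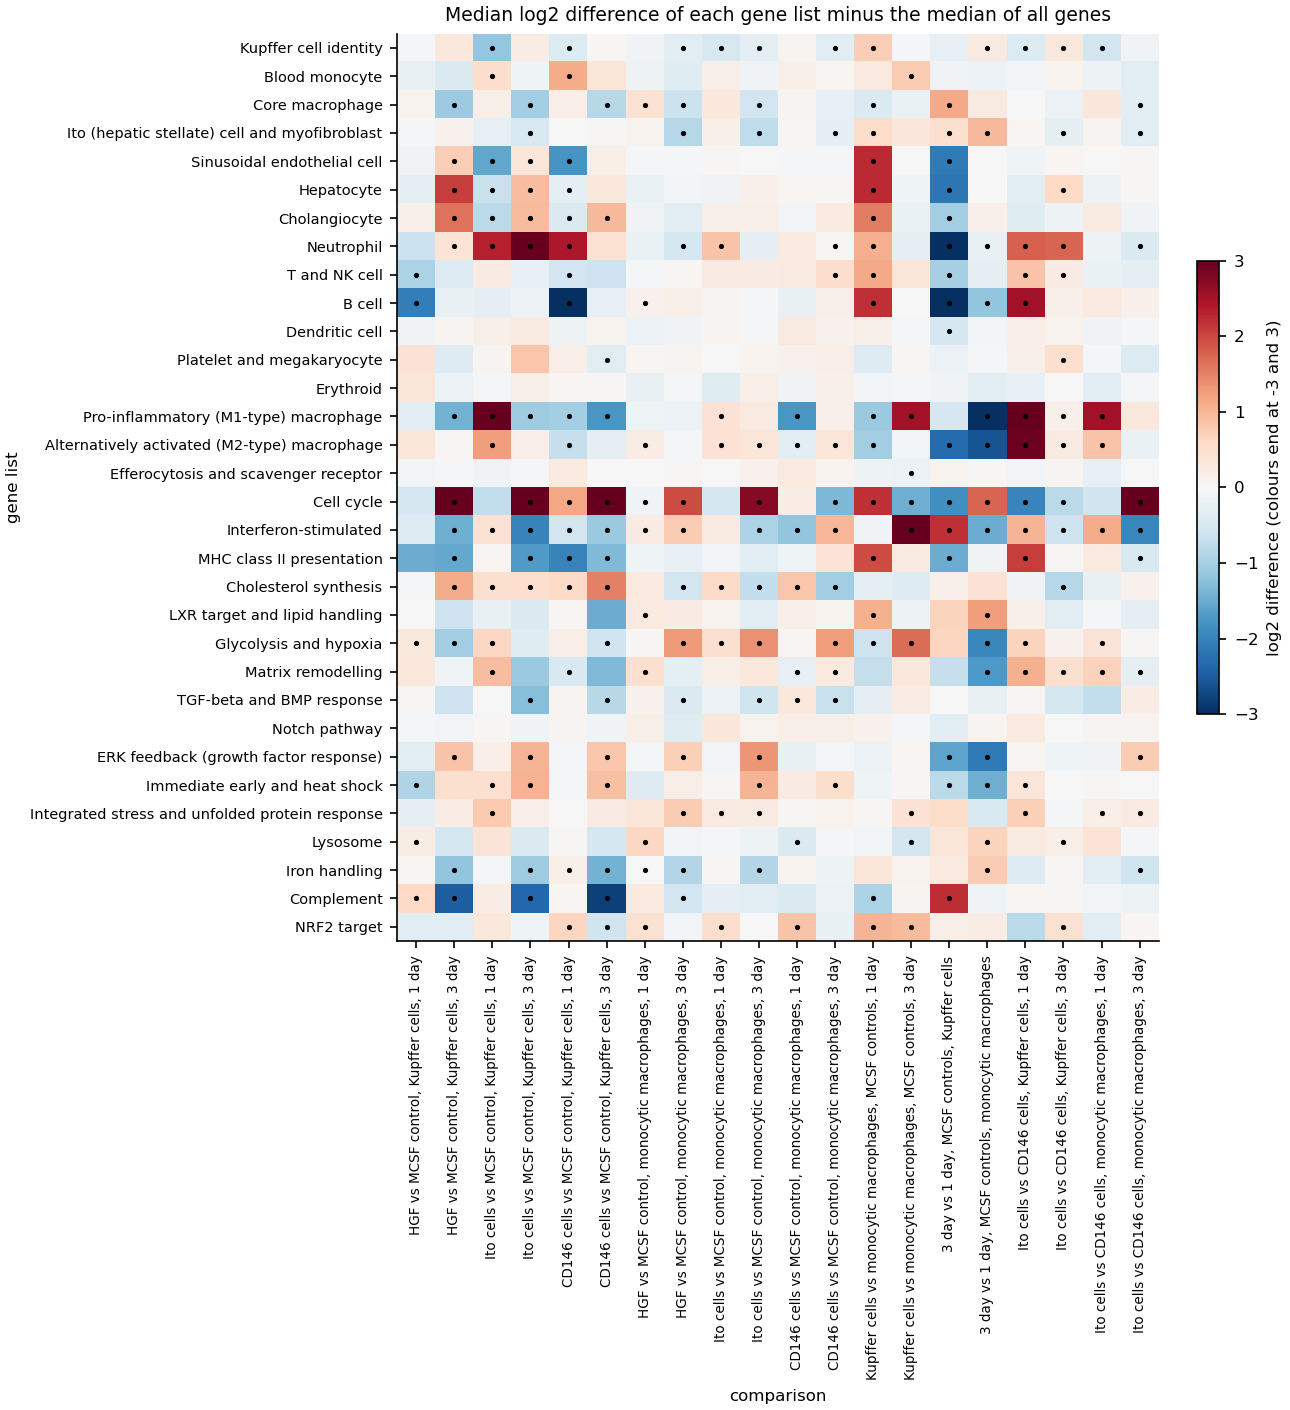
Colours give the median log2 difference of each gene list minus that of all genes, for 20 comparisons of 2 groups. Black dots mark camera adjusted p under 0.05 (preset correlation). The cell cycle list stands at 5.46 for CD146 cells in Kupffer cells after 3 days (1 control array sets the monocytic value).

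**Figure D4:**
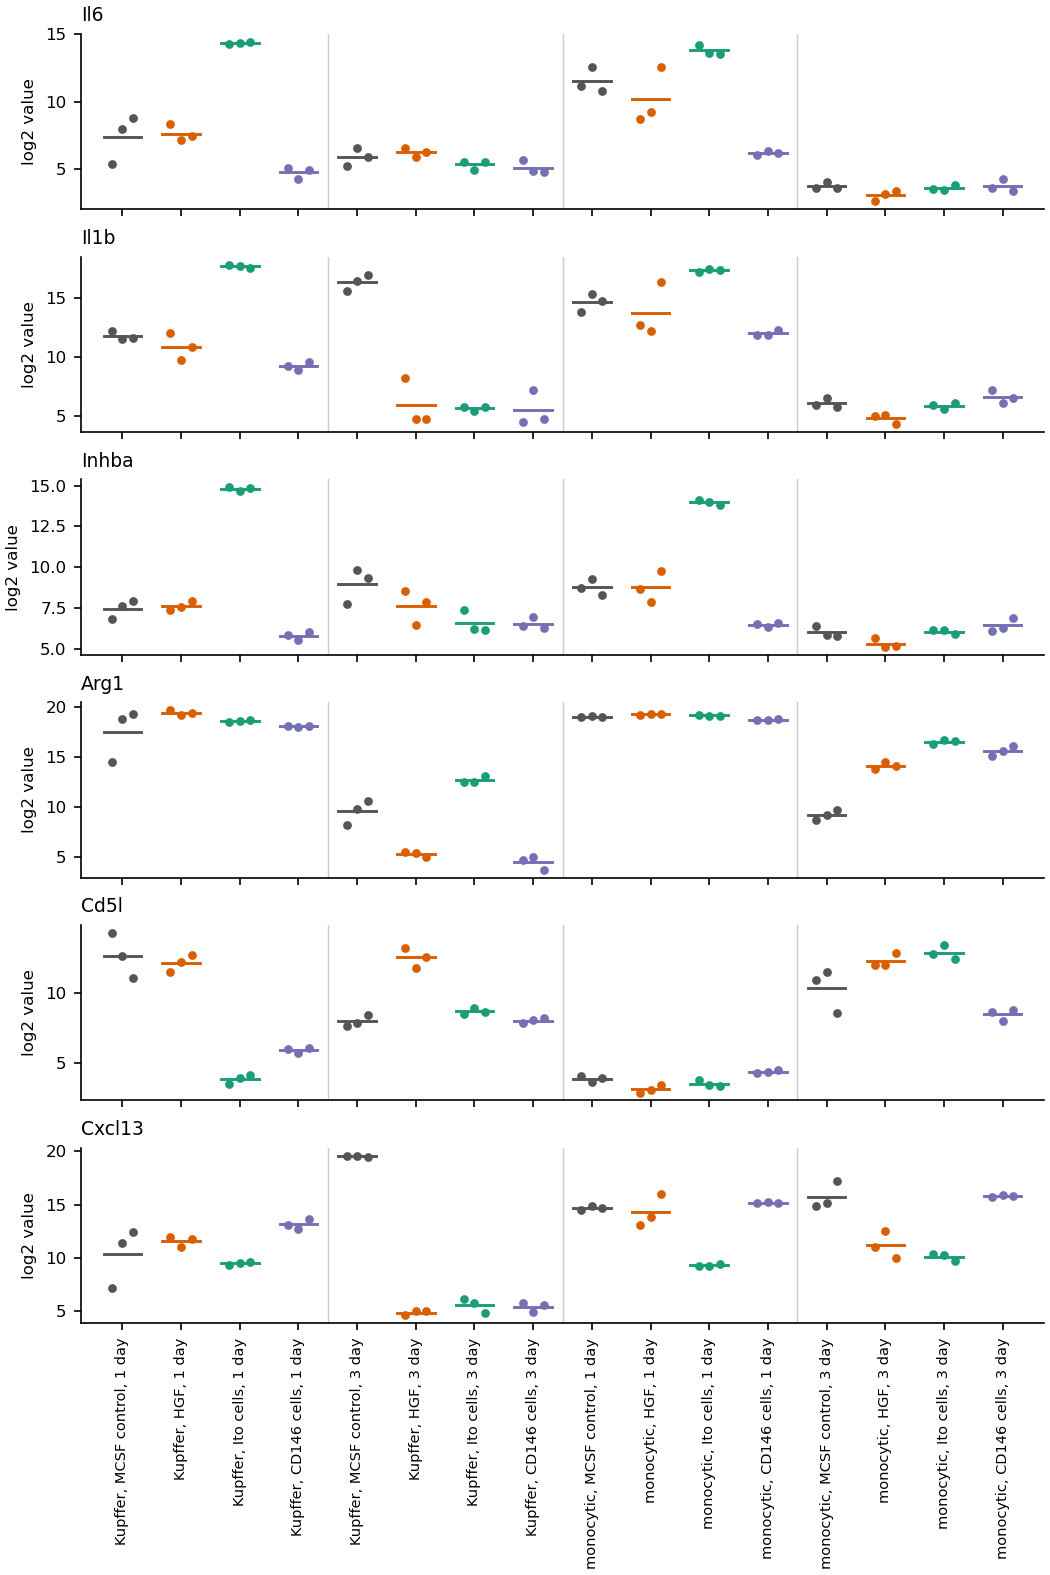
Each point is the log2 value of an array and each bar the mean of a group of 3, for Il6, Il1b, Inhba, Arg1, Cd5l and Cxcl13. Mean Il6 lies at 14.34 ± 0.09 in Kupffer cells after 1 day with Ito cells and at 7.37 ± 1.77 in their control (± SD).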

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

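The 6 comparisons of responses and their splits were planned, and the parting of the splits by the grouping they keep and the tests of explanations further down were chosen only after the results were seen.

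The limma contrast of the responses of both cell types found genes that differed between them for every addition and time, and the differences are those of the Kupffer response minus the monocytic one in log2 units. For HGF after 1 day 4515 genes differed, among them, before the median shift is taken off, Cir1 (-3.49), Tnfrsf13c (-3.44) and Hnrnpll (-2.98); 3 of 100 splits within each cell type, the real one included, gave as many (highest other 5628). For HGF after 3 days it was 2964, with Krt7 (11.30), Clu (11.26), Lmo7 (9.32), Susd2 (-12.52), Ch25h (-11.89) and Cxcl13 (-10.09), and 7 of 100 splits gave as many (highest other 4795). For Ito cells after 1 day it was 730, with Atp6v0d2 (6.14), Chil3 (5.12), Cxcl10 (5.05), Il6 (4.68), Cd5l (-8.51), Adgrl4 (-8.02) and F8 (-5.94), and 11 of 100 splits gave as many (highest other 6769). For Ito cells after 3 days it was 1706, with Ngp (12), Slc40a1 (10.98), Mpo (10.86), Ch25h (-13.25), Susd2 (-12.65) and Prg4 (-11.50), and 6 of 100 splits gave as many (highest other 4819). For CD146 cells after 1 day it was 171, with Ngp (3.77), Elane (3.62), Cd5l (-7.26), Cd55b (-5.51) and Igfbp7 (-5.14), and 6 of 100 splits gave as many (highest other 784). For CD146 cells after 3 days it was 3545, with Ube2c (11.92), Cdca3 (10.56), Cxcl13 (-14.16), Susd2 (-12.75) and Ly6i (-12.50), and 2 of 100 splits gave as many (highest other 3906). All other splits with as many genes kept the real grouping of 1 or both cell types, whose own response then enters the contrast, so these shares do not decide on chance; splits that mixed the groups of both cell types gave at most 2283, 92, 2, 5, 18 and 1 genes in the order above.

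Outside the named genes, 453 of 2634 probe sets without a gene name were at least 2-fold higher, past the test, in 1 or more of the 12 comparisons with a control.

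The monocytic HGF arrays of 1 day lay below their control over most genes, by -0.55 in the median. The negative control probes, which measure no transcript, were lower by -0.61 (SD within groups 0.09), and by -0.61 and -0.35 in the monocytic and Kupffer Ito arrays of 1 day, so arrays not put on one scale are a candidate cause. These probes were also lower where the median moved by under 0.1, by -0.25 to -0.35 in 4 comparisons of 3 days, so they do not follow the level of the genes alone. Less RNA of most genes in the cells stays open: the brightest 25 percent of genes moved by -0.29 and the dimmest by -0.76, and the groups and the level of the arrays cannot be told apart. An effect of HGF on the total RNA was not tested.

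The Kupffer control of 3 days stood apart from the other Kupffer cultures of 3 days, by -1.03 in the mean of the hepatocyte and endothelial lists. An exchange of labels with the monocytic control of 3 days would raise these genes in that control, but they differed from the other monocytic groups by -0.0506, against a gap of 0.87 between the cell types (SD 0.21). Macrophage RNA thinned out by RNA of other cells would lower all core macrophage genes alike, but with HGF their differences had an SD of 2.14 (median SE 0.29) and ranged from -7.04 to 0.03. Neither test excludes an exchange with a sample outside the series, or added or carried-over cells as a part of the change. As annotated, this control, like every other control, had more days of MCSF than the additions, a candidate explanation that was not tested.

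Kupffer control 1 day replicate 1 and Kupffer HGF 1 day replicate 2 stood apart from their groups. In the control array the poly-A controls, added to the RNA before labelling, were higher than in the rest of its group by 2.40 (SD 0.66 and largest 2.09 over the arrays of other groups), which is consistent with a low RNA input. In the HGF array they differed by -0.78, which argues against it there. Hybridisation controls were 1.37 higher in the control array and 1.44 in the HGF array (largest elsewhere 1.10). A lower share of macrophages in the control array would raise the genes of every other cell type alike, but the deviations of their lists spanned 7.11 (largest elsewhere 1.29), from -5.55 for B cells to 1.56 for endothelial cells. Such a change of the mix and a culture with fewer B cells stay open, and no biological explanation was tested.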

How the results depend on the processing

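The alternatives of this part had been chosen before the data were examined, except the fits without the 3 arrays that stood apart, which were chosen after their values were seen. Another Kupffer control of 3 days, in place of the one all Kupffer comparisons of 3 days share, was not run, since the table holds none.

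All 26 counts stayed within 1.5 times of the reported ones with a trend and robust variance model, with all probe sets, and with the replicate number as a block, although the numbers do not pair the arrays. Array weights moved 19 counts, all upward: in Kupffer cells after 1 day 5133 with HGF, 9044 with Ito cells and 4429 with CD146 cells, in monocytic macrophages after 3 days 4442 with HGF, 5016 with Ito cells and 1597 with CD146 cells, in monocytic macrophages after 1 day 6284 with Ito cells and 1875 with CD146 cells, between the controls 8299 of 1 day and 4093 of 3 days, over time 9333 in Kupffer cells, between Ito and CD146 cells 8651 in Kupffer cells after 1 day, 2787 in Kupffer cells after 3 days, 8190 in monocytic macrophages after 1 day and 3747 in monocytic macrophages after 3 days, for the difference in response after 3 days 4817 to HGF and 3017 to Ito cells, for the difference in response after 1 day 3757 to Ito cells and 1543 to CD146 cells. With a 2-fold change required as well, the counts were in Kupffer cells after 1 day 1794 with HGF and 2379 with Ito cells, in monocytic macrophages after 1 day 2643 with HGF and 1291 with Ito cells, between the controls 2480 of 1 day, over time 3985 in Kupffer cells and 3630 in monocytic macrophages, between Ito and CD146 cells 2749 in Kupffer cells after 1 day and 1796 in monocytic macrophages after 1 day; fewer genes can meet 2 conditions than 1. With only the arrays compared, and so their own spread, they were in Kupffer cells after 1 day 0 with HGF, 1614 with Ito cells and 78 with CD146 cells, in monocytic macrophages after 3 days 1294 with HGF, 1410 with Ito cells and 205 with CD146 cells, in monocytic macrophages after 1 day 4948 with Ito cells and 1404 with CD146 cells, between the controls 917 of 1 day, over time 3311 in Kupffer cells, between Ito and CD146 cells 8162 in Kupffer cells after 1 day, 1839 in Kupffer cells after 3 days and 7359 in monocytic macrophages after 1 day, for the difference in response after 1 day 561 to HGF, 371 to Ito cells and 70 to CD146 cells. The single 0 had 1753 genes at an unadjusted p under 0.05 by limma. The cause of the moves under array weights and with only the arrays compared was not tested.

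Quantile normalization gave in monocytic macrophages after 1 day 435 with HGF and 1759 with Ito cells, between Ito and CD146 cells 2405 in monocytic macrophages after 1 day, for the difference in response after 1 day 1053 to HGF, and median centring in monocytic macrophages after 1 day 633 with HGF and 1434 with Ito cells, between Ito and CD146 cells 2033 in monocytic macrophages after 1 day, for the difference in response after 1 day 2614 to HGF; both set the level of whole arrays, which is where these comparisons differed. Without the dimmest 25 percent of genes the counts were in monocytic macrophages after 1 day 3319 with HGF, for the difference in response after 1 day 1194 to HGF, from fewer genes. The range of the groups' 5th percentiles was 0.85 and 0.51 after median centring.

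Leaving out an array in turn, the remaining pair being assumed to vary like the other groups, moved counts by over 1.5 times in these cases, given as lowest to highest: in Kupffer cells after 1 day 901 to 5412 with HGF and 433 to 1063 with CD146 cells, in monocytic macrophages after 3 days 1239 to 3153 with HGF, 1262 to 3065 with Ito cells and 246 to 510 with CD146 cells, in monocytic macrophages after 1 day 1793 to 2268 with Ito cells and 280 to 316 with CD146 cells, between the controls 2365 to 4631 of 1 day, between Ito and CD146 cells 351 to 516 in Kupffer cells after 3 days and 2375 to 2931 in monocytic macrophages after 1 day, for the difference in response after 1 day 420 to 1465 to Ito cells and 114 to 265 to CD146 cells. Without the 3 arrays that stood apart the counts were in Kupffer cells after 1 day 1264 with HGF and 1685 with CD146 cells, in monocytic macrophages after 3 days 4354 with HGF, 4064 with Ito cells and 978 with CD146 cells, for the difference in response after 1 day 457 to CD146 cells. Fewer arrays remained in these fits, and otherwise the cause was not tested.

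Of 832 tests of lists camera called 321, and 85 with the correlation estimated from the arrays. The core macrophage list in monocytic macrophages after 1 day with HGF turned from up to down under fry, with a median of -0.10 (adjusted p = 0.952), since fry does not set a list against the other genes. Without monocytic control 3 day replicate 3, and without the 3 arrays, the camera direction of the cell cycle list turned from down to up for CD146 cells in monocytic macrophages after 3 days (median -0.11; -2.10 without replicate 1, adjusted p = 0.516 and 0.615) and between the controls of 3 days (median -0.0495; -2.12 without replicate 2, adjusted p = 0.63 and 0.664): this array carried the cell cycle genes of that control. Of 458 passing values of named genes, 24 lost their call without some array, 44 with only the arrays compared, 4 after quantile normalization, 3 after median centring and 9 without the 3 arrays, and of 104 list calls 10, 4, 3, 0 and 5. A gene near the 5th percentile of an array cannot be measured lower, which limits the falls that can be seen.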

Other observations

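The splits of this part had been planned, and no other test is reported here. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. HGF in Kupffer cells after 1 day gave 3421 genes and the highest other split 4953, so that 2 of 10 splits gave as many; this points to a structure of these 6 arrays other than the addition, in which replicate 1 of the control and replicate 2 of HGF stood apart. In the other comparisons of 2 groups 1 of 10 splits, the real one, gave as many genes, and the real count and the highest other count were in Kupffer cells after 3 days 5386 and 454 with HGF, 5219 and 2 with Ito cells and 5147 and 5 with CD146 cells, in Kupffer cells after 1 day 4584 and 152 with Ito cells and 737 and 609 with CD146 cells, in monocytic macrophages after 1 day 7307 and 6 with HGF, 3029 and 1 with Ito cells and 455 and 0 with CD146 cells, in monocytic macrophages after 3 days 2540 and 775 with HGF, 2431 and 628 with Ito cells and 468 and 115 with CD146 cells, between the controls 4157 and 113 of 1 day and 2355 and 205 of 3 days, over time 6197 and 470 in Kupffer cells and 5716 and 83 in monocytic macrophages, between Ito and CD146 cells 5349 and 0 in Kupffer cells after 1 day, 601 and 0 in Kupffer cells after 3 days, 3858 and 0 in monocytic macrophages after 1 day and 2207 and 0 in monocytic macrophages after 3 days.

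Replicate 3 of the monocytic control of 3 days lay at a distance (mean SD of the differences) of 0.60 from the monocytic Ito arrays of 3 days, 0.66 from the HGF arrays and 0.73 from its own group. It had a cell cycle list mean of 11.13 (Ito group 10.82 ± 0.14 SD), but Arg1 and Id3 at 9.74 and 9.26, against 8.68 and 9.17 (Arg1) and 8.99 and 9.29 (Id3) in the rest of its group and means of 16.54 and 3.94 in the Ito group.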
